A study of Mus musculus with 72 samples.

How the data were processed

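Gene expression was measured in 30 libraries from hippocampal tissue of adult C57BL/6J mice aged 4 to 6 months, and H3K4me3 and H3K4me1, methylation marks of histone H3, were measured in 38 libraries of chromatin from fixed neuronal nuclei sorted by FACS. Per the labels, RNA came from whole tissue by TRIZOL and TruSeq RNA libraries, and chromatin libraries used the NEBNext Ultra kit. Animals carried a conditional knockout (cKO) of Kmt2a or of Kmt2b, genes of H3K4 methyltransferases, and each line had its own controls. Of the 72 samples of the series, 68 had a processed file that was used here, and the 4 input samples were not analysed here.

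The deposited expression files hold whole-number counts of reads per Ensembl gene, and those of the Kmt2b line end with counters of reads not assigned. In the 19 Kmt2b libraries 9.54 to 11.12% of reads fell in no gene, 28.43 to 31.65% were not uniquely aligned and 56.0 to 60.49% were assigned to genes. The aligner and counting tool of the expression data are not given in the sources used here. Of 38355 gene identifiers, 36602 matched a symbol in the annotation at hand. No count was recorded for the mitochondrially encoded genes, so the list of such transcripts had 0 measured members.

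Per the file headers, the deposited peak lists were made by MACS 2.1.0.20140616 on each library against 1 input library per genotype and line, with narrow peaks, a q threshold of 0.1 and 1 tag kept per position. The labels name MACS2 and the mm10 genome build. Per the file headers, each peak has a tag pileup at its summit (a signal), a -log10 p and a -log10 q, a fold enrichment over the local input background (a ratio), and a length in bp (another unit). Because every cKO library of a line was compared with another input than its controls, genotype and input cannot be told apart in the peak calls. Peak lists hold no reads, so counts per region could not be had, and the measure used here was the length covered by peaks. That measure reads both the presence of a peak and its width, and a mark below the calling threshold counts as 0.

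Expression was compared within each line with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr on genotype, the quasi-likelihood F-test, labelled sex as a covariate and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The difference between lines was tested in 1 fit of all 30 libraries as the cKO effect in the Kmt2a line minus that in the Kmt2b line. Log2 changes are cKO over control throughout, and levels are library-scaled counts (CPM) from edgeR with their standard deviation (SD). Errors of log2 changes are standard errors (SE). For limma they come from the fit. For edgeR they were derived as the absolute log2 change divided by the square root of the F statistic. A total of 29 gene lists with at least 3 measured members were tested with camera of limma 3.58.1 with the preset correlation of 0.01 between genes, and beside it with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, in 1 direction. DESeq2 1.42.0 served as the second tool.

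For the chromatin data, peaks on chromosomes 1 to 19, X and Y were merged per line and mark, and a region was tested when at least 2 libraries of either group had a peak. The covered length plus 200 bp was taken to log2 and tested with limma (trend and robust variance, labelled sex as a covariate). Promoters were windows of 2 kb on either side of a gene end of protein-coding and lncRNA genes in the RefSeq table of mm10. The table at hand has no strand, so the promoter was taken as the gene end with more H3K4me3 cover over all 19 H3K4me3 libraries, not as the 5' end that had been planned. Among 19994 genes with a marked end, 2504 had both ends covered to at least 50% of each other, and for these the choice is less sure. A gene with an unmarked or weakly marked 5' end could also be given its other end. Such genes are not among the 2504 and could not be counted. Number of peaks, covered length and median width were compared with two-sided exact permutation tests of the difference of means. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

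Genes and promoters were named by a rule fixed before the data were examined, as were the comparisons, the tests, the gene lists and most alternatives. Per line the rule took the targeted gene and its paralogue, the 8 genes of smallest p in each direction with a mean of at least 1 CPM, the 4 largest changes in each direction among genes with all cKO libraries on 1 side of the control mean, and up to 3 members of each list whose test or any of whose members passed. For promoters it took the 6 of smallest p per direction and 4 with a peak in all libraries of 1 genotype and none of the other. Predicted genes without a given name were not named, and some genes that the rule selects are not reported here. Genes named outside this rule are marked as chosen after their values were seen. The tests of gene lists on promoters, of the promoter difference between lines, and the fits within lanes and alignment batches were added after the data were seen.

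The tests were tried on simulated data made from the spread of these libraries. Noise was drawn independently, with no effect shared by a whole library. Promoter changes were planted only among the most widely covered promoters, so those rates do not hold for narrower ones. At log2 changes of 0.5, 1 and 2 the expression test recovered 40, 88 and 100% of changed genes in the Kmt2a line and 68, 84 and 98% in the Kmt2b line. For H3K4me3 promoters at log2 changes of 0.5 and 1 it recovered 4 and 80% in the Kmt2a line and 74 and 96% in the Kmt2b line. For H3K4me1 promoters at a log2 change of 1.5 it recovered 42% in the Kmt2a line and 6% in the Kmt2b line. Alternatives covered normalization, the expression filter, the test, sex as a covariate, a block for the replicate number, each library left out once, stricter peak thresholds, equal peak numbers, the pseudocount, the overlap and the promoter window. The labels do not say that replicate numbers pair animals. In the expression data a control correlated best with the cKO library of its own number in 2 of 5 cases in the Kmt2a line and 2 of 8 in the Kmt2b line, so the replicate block was kept only as an alternative.

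Sequencing lanes are given for part of the chromatin libraries. In the Kmt2b line H3K4me3 libraries of females ran on lane 4 and of males on lane 8, so lane and sex cannot be told apart there. Together 2 pseudogenes were counted at over 1 CPM in 12 of the 19 Kmt2b expression libraries and in none of the other 7, which was read as a difference in alignment or annotation between 2 batches. Batch A held 3 control and 4 cKO libraries and batch B held 5 control and 7 cKO libraries.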

Results

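The series asks whether Kmt2a and Kmt2b act in memory function through different transcriptional programs, and compares adult mice that lack either enzyme in hippocampal CA neurons with controls of the same line. Expression libraries numbered 5 control and 6 cKO in the Kmt2a line and 8 control and 11 cKO in the Kmt2b line. H3K4me3, a mark of active promoters, and H3K4me1, a mark of enhancers and promoter flanks, were each profiled in 5 control and 3 cKO libraries of the Kmt2a line and in 6 control and 5 cKO libraries of the Kmt2b line. Both sexes were present in every group. Total gene counts ranged from 4.96 to 7.65 M in the Kmt2a line and from 13.82 to 33.51 M in the Kmt2b line. The Kmt2b comparison thus has both more libraries and more counts. Unique tags of the H3K4me3 libraries ranged from 2.64 to 10.68 M in the Kmt2a line and from 3.1 to 9.04 M in the Kmt2b line. Those of H3K4me1 ranged from 4.61 to 12.81 M and from 14.62 to 23.71 M.

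The first comparison asks which transcripts depend on Kmt2a. Counts of the Kmt2a gene itself were 184 ± 22.9 CPM (SD, n = 5) in controls and 160 ± 28.4 CPM (SD, n = 6) in cKO, a log2 change of -0.21 ± 0.12 (edgeR adjusted p = 0.374), and the paralogue Kmt2b had a log2 change of 0.16 ± 0.12. A count over the whole gene in whole tissue does not measure the deleted part, so it is no check of the knockout. Wfs1, a protein of the endoplasmic reticulum and a marker of CA1 pyramidal neurons, fell from 346 ± 61.7 to 148 ± 43.5 CPM, a log2 change of -1.26 ± 0.17. Nts, the precursor of the neuropeptide neurotensin, fell from 7.06 ± 3.13 to 0.281 ± 0.475 CPM. Ntsr1, a neurotensin receptor, rose from 5.33 ± 0.794 to 13.9 ± 3.29 CPM. Oxr1, which protects cells from oxidative damage, fell by 0.91 ± 0.10 on the log2 scale, from 282 ± 40.5 to 147 ± 18.8 CPM, in 6 of 6 cKO libraries.

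Among the other genes that fell in the Kmt2a cKO were Sema3e (-0.92 ± 0.11) and Robo1 (-0.55 ± 0.08), both of axon guidance, the secreted ligand Wnt2 (-1.29 ± 0.16), the ubiquitin ligase March1 (-0.84 ± 0.11) and Klhl13 (-0.61 ± 0.09). The largest decreases also included Rxfp1, a relaxin receptor (-2.96 ± 0.61), Glra2, a glycine receptor subunit (-1.65 ± 0.31), and Scgn, a calcium-binding protein (-1.46 ± 0.31). With 1 library left out at a time, Rxfp1 no longer passed in 8 of 10 fits, Glra2 in 4 of 11 and Scgn in 9 of 11. Genes that rose included Hes1, a transcriptional repressor downstream of Notch, from 6.07 ± 1.39 to 16.6 ± 3.07 CPM (1.44 ± 0.17). Stra6, a receptor for retinol-binding protein, rose by 1.46 ± 0.17 on the log2 scale, and Abca4, a retinoid transporter, by 1.40 ± 0.31. Abca4 no longer passed in 10 of 11 fits that each left out 1 library. The abundant synaptic genes Nptxr, a neuronal pentraxin receptor (882 to 1312 CPM, 0.58 ± 0.08), and Cpne6, a calcium-dependent membrane-binding protein (425 to 644 CPM, 0.60 ± 0.09), rose as well. Inpp4b (0.95 ± 0.13), Rtn4rl2 (0.63 ± 0.10) and C1qtnf12 (0.78 ± 0.12) completed the genes of smallest p.

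**Figure D1:**
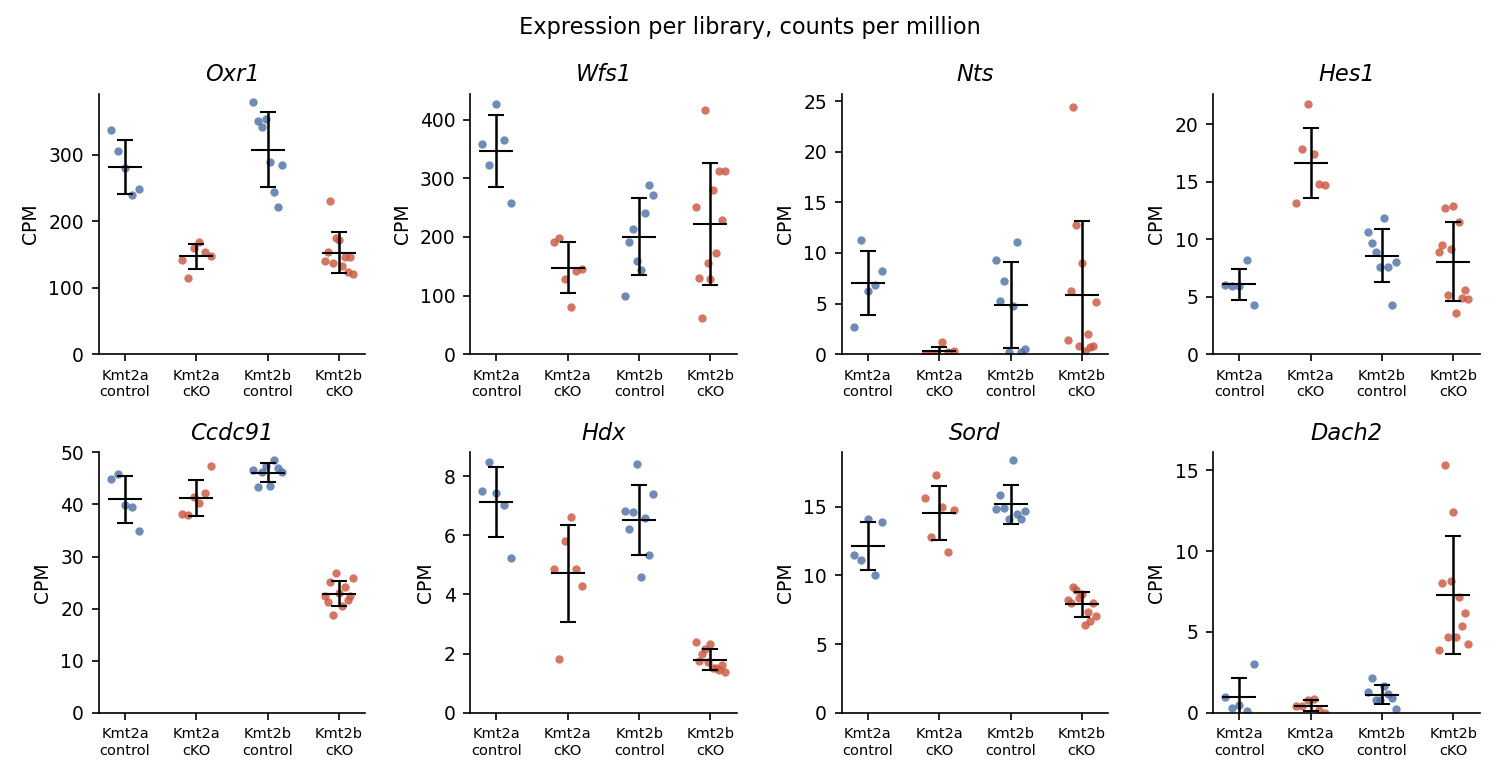
CPM of 8 genes in each expression library, by line and genotype; points are libraries, horizontal bars the mean and error bars the SD. Oxr1 lay at 282 CPM in controls and 147 CPM in cKO of the Kmt2a line, Wfs1, Nts and Hes1 changed in the Kmt2a line, and Ccdc91, Hdx, Sord and Dach2 changed in the Kmt2b line.

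Of 17 oligodendrocyte markers 2 fell in the Kmt2a cKO, among them Ugt8a, an enzyme of myelin lipid synthesis (-0.83 ± 0.17). None rose, 15 did not pass, and 13 fell when adjusted over the list alone. All 17 had a negative sign (camera adjusted p = 5.22e-09). Members of this list vary together, and the adjusted p = 0.708 with an estimated correlation. Oligodendrocyte precursor markers had 0 of 10 members past the test, 1 lower when adjusted over the list alone, and a camera adjusted p of 0.0198 (adjusted p = 0.708 with an estimated correlation), for example Vcan at -0.46 ± 0.12 (edgeR adjusted p = 0.0864). All 11 meningeal fibroblast markers were positive in sign with 0 past the test and 1 higher over the list alone (camera adjusted p = 0.0239, adjusted p = 0.809 with an estimated correlation). Of 19 endothelial and mural markers only Acta2, a smooth muscle actin, rose (0.92 ± 0.18). The mean and test of that list were positive and its median was -0.02. With 1 library left out at a time, Ugt8a no longer passed in 7 of 11 fits and Acta2 in 8 of 11.

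Of the lists of neuronal genes in the Kmt2a cKO none passed with an estimated correlation (lowest adjusted p = 0.573) or with fry (lowest adjusted p = 0.108). Of 18 genes of GABA receptors, synthesis and transport 0 passed over all genes and 5 fell when adjusted over the list alone (camera adjusted p = 0.000593), with Gabra5 at -0.49 ± 0.12 and Gabrg3 at -0.71 ± 0.16. Of 30 potassium channels Kcnh7 fell (-0.87 ± 0.16), 29 did not pass and 3 fell over the list alone (camera adjusted p = 0.00514). Kcnh7 no longer passed in 6 of 11 fits that each left out 1 library. Of 10 CA1 pyramidal markers Wfs1 fell, 9 did not pass and 3 fell over the list alone (camera adjusted p = 0.0119). Of 18 interneuron markers 0 passed and 1 fell over the list alone, Reln being at -0.36 ± 0.08 (camera adjusted p = 0.0119). Ribosomal protein genes had a positive median with 0 of 51 past the test (median log2 change 0.12, camera adjusted p = 0.00408). So had synaptic vesicle genes, with 0 of 28 past the test and 3 higher over the list alone, among them Syn1 at 0.26 ± 0.07 (camera adjusted p = 0.0291). With an estimated correlation or with fry, none of the 29 lists passed in this line.

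Single members moved in lists whose test did not pass. In 11 fits that each left out 1 library, Cacnb3 and Serpina3n no longer passed in 9 and Plekhg1 in 7. Cdhr1 no longer passed in 6 of them, Homer2 in 4, Calb1 in 3 and Camk4 in 1. Homer2, a postsynaptic scaffold, fell (-0.52 ± 0.10) with 25 postsynaptic genes not past the test. In the list of sodium and calcium channels Cacnb3, a calcium channel subunit, rose (0.41 ± 0.09). Calb1, a calcium buffer, rose (0.99 ± 0.17) and the kinase Camk4 fell (-0.69 ± 0.11) among 29 genes of memory-related signalling. Serpina3n, a marker of reactive glia, fell (-0.66 ± 0.14; the list's median was 0.04, its mean -0.03 and its test up), the dentate granule marker Cdhr1 rose (1.33 ± 0.26; this list's mean was 0.01, its median -0.09 and its test up), and Plekhg1 fell (-0.66 ± 0.13) among 13 striatal and thalamic markers.

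Over all genes, 48 rose and 88 fell of 13318 tested in the Kmt2a line (edgeR), and 2454 had an unadjusted p under 0.05. DESeq2 called 499, and the fit with a block for the replicate number 61. The count rests on few animals: it was 36 without control replicate 1, 38 without control 2, 16 without control 3, 29 without control 4, 66 without cKO replicate 1, 37 without cKO 2, 82 without cKO 6 and 388 without cKO 5. Sex-linked transcripts went against the labelled sex in 6 of the 11 libraries, and without those 6 the count was 514, of which 79 were among the 136.

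The second comparison asks which transcripts depend on Kmt2b. Counts of Kmt2b itself were 48.1 ± 3.36 CPM (SD, n = 8) in controls and 44.8 ± 4.85 CPM (SD, n = 11) in cKO, a log2 change of -0.11 ± 0.07 (edgeR adjusted p = 0.561), again over the whole gene, and Kmt2a had 0.00 ± 0.04. Ccdc91, a protein of Golgi trafficking, fell from 46.1 ± 1.82 to 22.9 ± 2.37 CPM, a log2 change of -1.03 ± 0.06, in 11 of 11 cKO libraries. The homeobox gene Hdx fell from 6.52 ± 1.18 to 1.80 ± 0.359 CPM (-1.85 ± 0.13), and Sord, sorbitol dehydrogenase, from 15.2 ± 1.41 to 7.88 ± 0.917 CPM (-0.95 ± 0.07). Dazl, an RNA-binding protein of germ cells, fell by 2.03 ± 0.19 and the meiotic helicase gene Hfm1 by 2.1 ± 0.19 on the log2 scale. Oxr1 fell here too, from 307 ± 56.9 to 152 ± 31.1 CPM (-1.01 ± 0.12), also within alignment batch A (-1.07 ± 0.19; edgeR adjusted p = 0.274 with 3 control and 4 cKO libraries) and batch B (-1.0 ± 0.12; adjusted p = 0.00141).

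Further genes that fell in the Kmt2b cKO were the anoctamin Ano10 (-0.64 ± 0.05), Wdsub1 (-0.96 ± 0.07), the DNA polymerase subunit gene Pole4 (-0.92 ± 0.07), Wdr17 (-1.19 ± 0.10), Eda, ectodysplasin A (-1.09 ± 0.09), the sodium/proton exchanger gene Slc9b2 (-1.98 ± 0.27) and Igsf1 (-1.88 ± 0.27). Rises were fewer and mostly small. Ido2, a tryptophan-degrading enzyme, rose from 2.68 ± 0.378 to 9.79 ± 2.80 CPM (1.77 ± 0.14), and Dach2, a transcription cofactor, from 1.12 ± 0.583 to 7.29 ± 3.63 CPM (2.70 ± 0.34). Col22a1, a collagen (0.91 ± 0.13), Atp2c2, a calcium pump (1.19 ± 0.21), and Spag17os (1.93 ± 0.47, from 0.401 CPM) rose. Pramef8 (0.36 ± 0.05), the mitochondrial iron importer Slc25a37 (0.30 ± 0.05), the kinase Wee1 (0.34 ± 0.06) and the chaperone Clgn (0.31 ± 0.05) rose by less.

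The clustered protocadherin beta genes, neuronal adhesion molecules encoded side by side on chromosome 18, were higher in the Kmt2b cKO. Of 21 measured members 6 rose, 0 fell and 15 did not pass, 11 rose when adjusted over the list alone, and all 21 had a positive sign. Pcdhb22 rose by 0.54 ± 0.08, Pcdhb17 by 0.46 ± 0.08 and Pcdhb20 by 0.40 ± 0.07 on the log2 scale. The list passed with camera (adjusted p = 3.97e-14) and with fry (adjusted p = 0.0266), and the adjusted p = 0.4 with an estimated correlation. These genes are similar copies in 1 cluster and are not independent. Reads not uniquely aligned were counted apart from the genes, so reads that match several copies may be missing from their counts.

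Markers of cell types changed little in the Kmt2b cKO. The dentate granule marker Cdhr1 fell (-1.36 ± 0.16; 11 others not past, camera adjusted p = 0.0441), and 0 of 18 interneuron markers passed (camera adjusted p = 0.0492); both lists had an adjusted p = 0.963 with an estimated correlation. The CA1 marker Spink8 rose (0.52 ± 0.13) with 9 CA1 markers not past the test. The water channel gene Aqp4 rose (0.30 ± 0.07) with 16 astrocyte markers not past, and Kl, klotho, fell (-1.16 ± 0.19) with 12 markers of choroid plexus and ependyma not past. The kinase Mapk3 fell (-0.39 ± 0.10) with 28 genes of memory-related signalling not past, and the transcription factor Irf1 fell (-0.59 ± 0.12) with 21 interferon-response genes not past. In 19 fits that each left out 1 library, Mapk3 no longer passed in 11, Aqp4 in 9 and Spink8 in 8. Oligodendrocyte, oligodendrocyte precursor, microglia, and endothelial and mural markers had 0 members past the test, with median log2 changes of -0.02, 0.01, 0.02 and 0.02. Lists of glutamate receptors, potassium channels, postsynaptic scaffolds, vesicle genes and activity-induced genes had 0 members past the edgeR test, with camera p from 0.127 to 0.531 before adjustment. The sign of median, mean and test was not the same for oligodendrocyte markers (median and mean negative, test up), vesicle genes (mean -0.01, median and test positive) and meningeal markers (median 0.15, mean 0.12, test down).

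Over all genes, 71 rose and 343 fell of 16187 tested in the Kmt2b line (edgeR), 1885 had an unadjusted p under 0.05, and DESeq2 called 607. The fit with a block for the replicate number called 196, females alone 181 and males alone 11. With the alignment batch as a term 434 were called, within batch B 161, of which 154 were among the 414, and within batch A 0, where 1262 had an unadjusted p under 0.05.

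To ask whether the programs differ, the cKO effects of the lines were tested against each other. Ccdc91, Sord and Dazl fell in the Kmt2b cKO while their log2 changes in the Kmt2a cKO were 0.02, 0.28 and -0.07, and the differences were 1.03, 1.21 and 1.97 (edgeR adjusted p = 4.94e-07, 4.23e-06 and 0.000527). Sema3e, March1 and Camk4 fell in the Kmt2a cKO with log2 changes of 0.10, 0.05 and 0.15 in the Kmt2b cKO, and the differences were -1.02, -0.90 and -0.86 (adjusted p = 0.00034, 2.65e-05 and 0.0055). Cdhr1 moved in opposite directions, up in the Kmt2a and down in the Kmt2b cKO, with a difference of 2.67 (adjusted p = 6.81e-06). For Wfs1, Nts and Wnt2 the difference did not pass (adjusted p = 0.0512, 0.0885 and 0.19). Over all genes the effects differed for 790 of 16698, 369 of them with the more positive effect in the Kmt2a line and 421 with the more negative, and DESeq2 called 1204. The count was 350 without Kmt2a control replicate 3, 495 without Kmt2a control 2, 388 without Kmt2a cKO replicate 2, 524 without Kmt2a cKO 6, 1373 without Kmt2a cKO 3 and 1473 without Kmt2b control replicate 4. The fit of all 30 libraries used 1 spread for both lines. In it 545 genes passed in the Kmt2a line, of which 105 were among the 136 of its own fit, and 420 passed in the Kmt2b line. The 790 thus cannot be set directly against the counts of the separate fits.

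The gene sets shared few genes, and about as many as independent sets would, so the overlap alone does not show separate programs. Of 13307 genes tested in both lines, 1 fell in both, Oxr1, where independent sets would share 1.97 (one-sided Fisher's exact test p = 0.865), and 0 rose in both. Cdhr1 and Tox3 rose in the Kmt2a and fell in the Kmt2b cKO (1.07 expected, p = 0.292), and 0 did the reverse. The difference of Oxr1 between lines was 0.08 ± 0.18 (edgeR adjusted p = 0.845). Across these 13307 genes, which are not independent replicates, log2 changes of the lines had a Pearson r of -0.09 and a Spearman rho of -0.21. These were computed for 3 gene sets. They were -0.209 and -0.24 for the 136 genes called in the Kmt2a line, and 0.027 and -0.031 for 357 called in the Kmt2b line. Genotype effects were also compared between sexes within each line: 0 genes passed with edgeR in the Kmt2b line (291 at an unadjusted p under 0.05; 0 passed and 388 with DESeq2) and 0 in the Kmt2a line (356 and, with DESeq2, 0 passed and 252), where the labelled sex is in doubt.

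For the H3K4me3 mark, the question is where methylation depends on each enzyme. In the Kmt2b cKO the promoter of Col11a1, a fibrillar collagen (mm10 chromosome 3, position 114030479), lost its peak: peaks covered 1456 ± 148 bp (SD, n = 6) of the window in controls and 0 bp in 5 of 5 cKO libraries. The promoter of Trim71, an RNA-binding ubiquitin ligase of early development (chromosome 9, 114564369), went from 1930 ± 39.8 to 40.8 ± 91.2 bp, a log2 change of -3.22 ± 0.20. Eps15, an endocytosis gene (chromosome 4, 109280175), Actrt3 (chromosome 3, 30599870) and the connexin gene Gjc1 (chromosome 11, 102819686) had 1026 ± 136, 1230 ± 335 and 883 ± 130 bp in controls and 0 bp in every cKO library. The shared promoter of the ribonuclease genes Ang and Rnase4 (chromosome 14, 51091077) fell by 2.85 ± 0.22 on the log2 scale. The promoter of Kmt2b itself changed by -0.18 ± 0.06 (limma adjusted p = 0.0775) and that of Kmt2a by 0.00 ± 0.05.

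Over all promoters, 2240 were covered over a shorter length in the Kmt2b cKO and 42 over a longer one, of 17246 tested (limma), so 13% of promoters were shorter. Those shorter in cKO were narrower already in controls, with a median cover of 853 bp against 1279 bp at the other promoters, and 278 of them had a peak in every control and in no cKO library. Tested within the lanes, 773 promoters were shorter in females alone and 548 in males alone, and 266 of the 2240 passed in both. Of the longer promoters 9 belonged to vomeronasal receptor genes such as Vmn1r148 (1.41 ± 0.27), Vmn1r129, Vmn1r100 and Vmn1r62, and 21 to predicted genes. Mrgpra2a, a sensory receptor gene, and Mat2a, which makes the methyl donor S-adenosylmethionine (2110 ± 179 to 2601 ± 176 bp, 0.28 ± 0.07), were also longer. The 42 became 26 without control replicate 5 or cKO replicate 1 and 21 without cKO replicate 5. The 6 named calls were lost in part with other settings, all within at least 1 lane. Vmn1r148 was not called without the sex term (adjusted p = 0.0686) nor, with Vmn1r62 and Mat2a, in windows of 1 kb (adjusted p = 0.208, 0.319 and 0.754). Mrgpra2a, Vmn1r62 and Mat2a were not called with equal peak numbers (adjusted p = 0.12, 0.314 and 0.178).

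**Figure D2:**
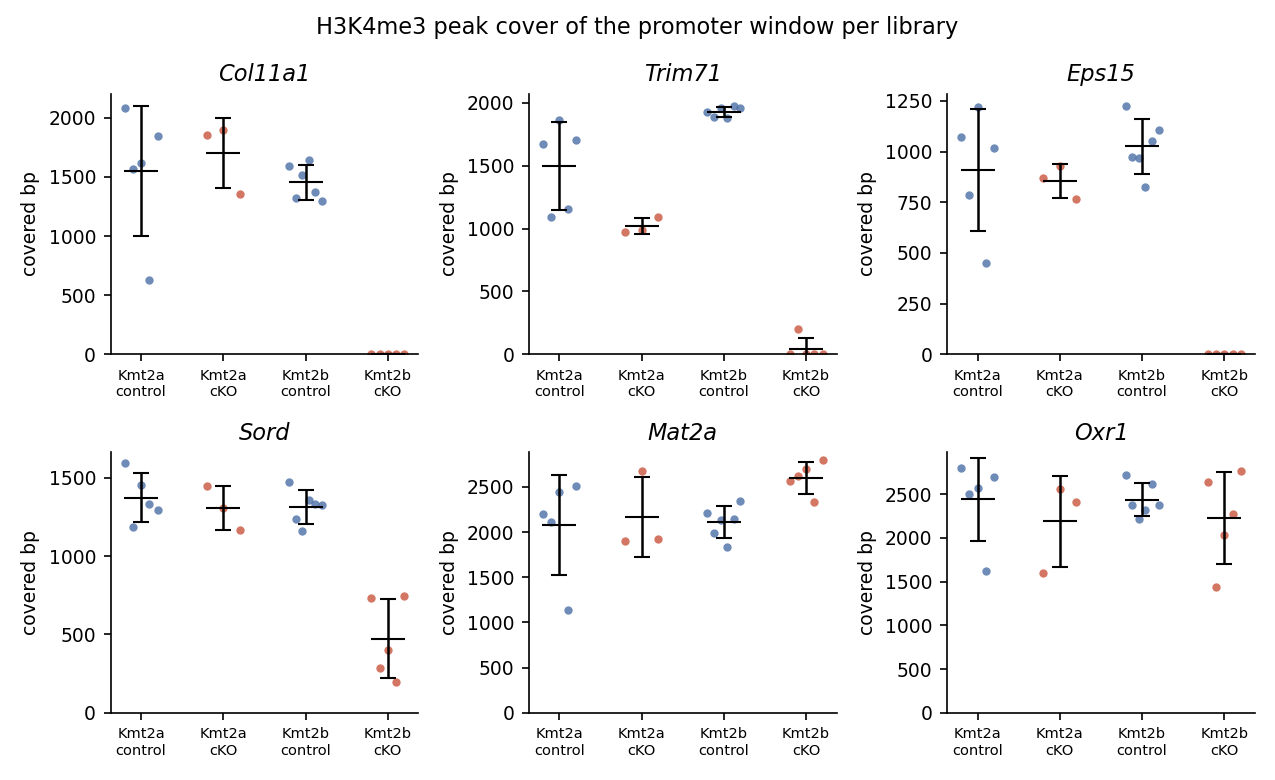
Length in bp covered by H3K4me3 peaks within 2 kb on either side of 6 promoters in each library, by line and genotype; points are libraries, horizontal bars the mean and error bars the SD. At Col11a1 and Eps15 all Kmt2b cKO libraries were at 0 bp, against means of 1456 and 1026 bp in the Kmt2b controls.

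Most merged regions that passed were shorter with the sexes pooled, but not in males alone. In the Kmt2b cKO 1860 regions were shorter and 248 longer of 58656 (limma), and 71.5% of the shorter regions lay within 2 kb of a gene end against 26.5% of all tested and 12.9% of the longer ones. A peak was present in all control and no cKO libraries at 478 regions and in all cKO and no control libraries at 57. Females alone gave 87 shorter and 0 longer regions, males alone 1558 shorter and 7666 longer. Of the 7666, 4005 lay on the Y chromosome, where the 2 male cKO libraries had 28.2 and 33.1% of their peaks and the 3 male controls 8.51 to 20.4%. Another 3196 lay on autosomes, against 1502 shorter autosomal regions, so in males alone longer regions outnumbered shorter ones off the Y chromosome too. The count of both directions was 1329 without cKO replicate 4. The 248 longer regions rest on single libraries: they numbered 147 without control replicate 3, 89 without control 5, 93 without control 6, 142 without cKO replicate 1, 388 without cKO 2 or cKO 3, 112 without cKO 4 and 85 without cKO 5, and 9 at a -log10 q of at least 10. Numbers of peaks were 44080 ± 7662 in controls and 56480 ± 18030 in cKO (SD; exact permutation p = 0.149). On autosomes they were 35780 ± 4852 and 40600 ± 7493 (exact permutation p = 0.238), and at a -log10 q of at least 10 they were 14680 ± 686 and 13130 ± 1609 (exact permutation p = 0.0823).

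In the Kmt2a cKO no H3K4me3 promoter passed. The promoters of smallest p were on the shorter side Tmco4, Popdc2 and Agbl2 (617 ± 278, 386 ± 152 and 356 ± 145 bp in 5 controls, 0 bp in 3 of 3 cKO), Gnb4, a G protein subunit gene (-1.65 ± 0.39), Htra1, a secreted protease gene (-1.41 ± 0.37), and Hmgb1 (-0.66 ± 0.17). On the longer side they were Speer4e (1.91 ± 0.42), Pcdhb14 (0 bp in 5 of 5 controls, 318 ± 98.6 bp in cKO), Speer4d (148 ± 330 to 1293 ± 876 bp) and Prmt5, an arginine methyltransferase gene (0.61 ± 0.19). Each had a limma adjusted p of 1. The promoter of Kmt2a changed by -0.01 ± 0.10. By limma 0 of 16851 promoters passed (234 at an unadjusted p under 0.05) and 0 of 33807 regions (2456), while 6 regions passed without control replicate 1 and 2 without control replicate 4. The number of promoters at an unadjusted p under 0.05 depended on the libraries and ran from 125 to 895 when each was left out once. It was 2019 with log2 tags as a covariate, and 0 promoters passed in any of these fits. Of changes simulated at the most widely covered promoters 80% were recovered at a log2 change of 1 and 4% at 0.5 in this line. Narrower promoters were not tried. The lack of calls thus does not show that the mark was unchanged.

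The difference between lines was tested for H3K4me3 promoters as well, a comparison added after the data were seen. Col11a1, Eps15 and Actrt3 differed by 3.21, 2.57 and 2.66 on the log2 scale, and Trim71 by 2.77, the Kmt2b cKO being the lower. These values include the 200 bp added before the log, on which they depend where the cKO libraries were at 0 bp. Over all promoters 585 were lower in the Kmt2b cKO relative to the Kmt2a cKO and 4 were higher, of 17828 (limma). The 4 were Agbl2 (-1.43, adjusted p = 0.00819; not among the promoters tested in the Kmt2b line), 2 predicted genes and, chosen after its value was seen, the myosin gene Myh14 (-2.16, adjusted p = 0.0466). The 2240 promoters shorter in the Kmt2b cKO had a median log2 change of -1.23 there and of -0.02 in the Kmt2a cKO, where 2229 were tested and 55.8% had a negative sign. The Kmt2b value comes from the libraries that selected these promoters, so its sign was given by the choice. Over all 16851 promoters tested in the Kmt2a line the median was -0.014. Of the 2240, 582 passed the test of the difference.

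**Figure D3:**
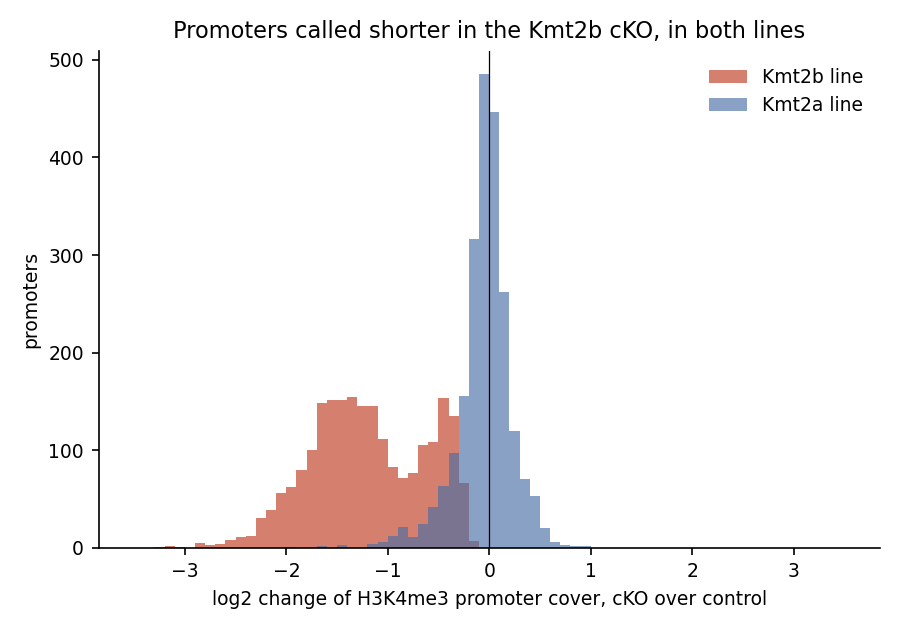
Number of promoters (vertical axis) by log2 change of H3K4me3 cover, cKO over control (horizontal axis), for the promoters called shorter in the Kmt2b cKO; red is the Kmt2b line and blue the Kmt2a line. The medians were -1.23 and -0.02. The promoters were selected in the Kmt2b libraries, so the sign of the first value was given by the choice.

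Promoter mark and expression were then set side by side in each line. In the Kmt2b cKO 5 of the 8 genes of smallest expression p among those that fell had a shorter promoter: cover changed by -0.66 at Ccdc91, -1.28 at Hdx, -0.58 at Ano10, -1.25 at Sord and -1.76 at Eda (log2). Wdsub1 (-0.63, limma adjusted p = 0.0558) and Pole4 (-1.01, adjusted p = 0.0509) did not pass and Wdr17 had no tested promoter. Among named genes chosen by size or list membership cover changed by -1.64 at Hfm1, -1.82 at Dazl, -1.71 at Irf1 and -2.14 at Kl (log2, all called shorter), and Slc9b2 and Igsf1 went from 488 ± 244 and 331 ± 223 bp to 0 bp in every cKO library. Col11a1, Trim71 and Actrt3 had expression changes of -1.75, -2.59 and -1.69, whereas Eps15 lost its peak with an expression change of 0.05 ± 0.07 (448 CPM in controls). Dach2 had a shorter promoter (229 ± 145 bp in controls, 0 bp in cKO) although its expression rose. At Oxr1 cover changed by -0.13 ± 0.12 (limma adjusted p = 0.576) in the Kmt2b and by -0.15 ± 0.19 (adjusted p = 1) in the Kmt2a cKO.

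Of 12611 genes in both tables of the Kmt2b line, 1522 had a shorter promoter and 302 fell in expression, and 161 did both, where independent sets would share 36.4 (one-sided Fisher's exact test p = 9.67e-70). Shorter promoters thus stood at 53.3% of the genes that fell. With genes that rose they shared 4 (6.28 expected, p = 0.888): Dach2, Mylk, Plin1 and Slc7a2. Of the 1522 genes 70.4% had a negative expression change, with a median log2 change of -0.10 against 0.01 for other genes (camera p = 2.51e-15, p = 0.000499 with an estimated correlation), so most shorter promoters went with little change of expression. Mark and expression came from sorted nuclei and from whole tissue of animals that the labels do not pair. In the Kmt2a line no promoter passed; the 200 promoters of smallest p on the shorter side had a median expression change of -0.03 (camera p = 0.0699), and the 200 on the longer side one of -0.04 (camera p = 0.821).

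**Figure D4:**
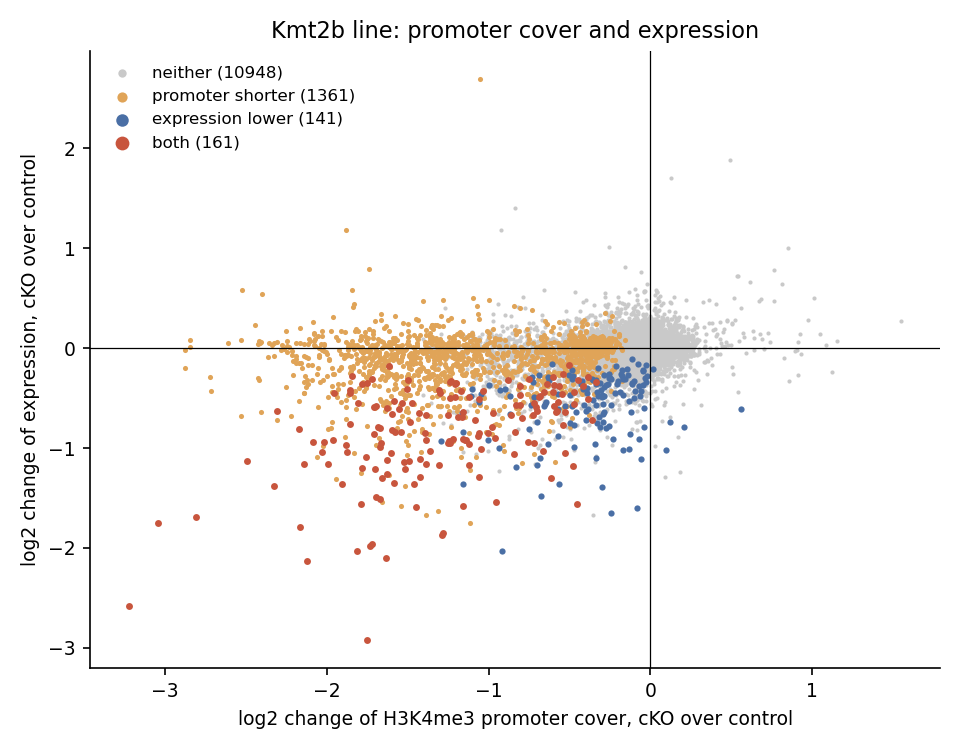
Log2 change of H3K4me3 promoter cover (horizontal axis) against log2 change of expression (vertical axis), cKO over control, for 12611 genes of the Kmt2b line; each point is a gene, coloured by which changes passed. The 161 genes with a shorter promoter and lower expression lie at the lower left, and 1361 had a shorter promoter but did not pass as lower in expression.

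For H3K4me1 few calls were made, in a comparison that recovered few simulated changes. At a log2 change of 1.5 these were 6% of widely covered promoters in the Kmt2b line and 42% in the Kmt2a line. In the Kmt2b cKO the promoter of Fcgr3, an immunoglobulin receptor of microglia and other immune cells (chromosome 1, 171065915), went from 2110 ± 387 bp in 6 controls to 127 ± 285 bp in 5 cKO, a log2 change of -3.13 ± 0.55 by limma, and its H3K4me3 cover was shorter too (-1.84 ± 0.39), while its expression in tissue changed by 0.07 ± 0.10. It was the only promoter of 12126 and lay in the only region of 44656 to pass (limma; 682 and 1189 at an unadjusted p under 0.05). These lists were thin, with 738 to 50932 peaks at 14.62 to 23.71 M tags. Without the 5 libraries with under 20000 peaks 2606 regions passed, 1998 of them longer, but 0 promoters; Fcgr3 then had a log2 change of -2.67 against -3.13 and an adjusted p of 0.569. No region passed without cKO replicate 1, 2 or 4, while 5 regions and 11 promoters passed without control replicate 2, and 2 promoters without cKO replicate 3.

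In the Kmt2a cKO 8 H3K4me1 regions were shorter and 0 longer of 152893 (limma), among them, chosen after their values were seen, 1 near the Notch ligand gene Jag2 (chromosome 12, 112914472 to 112919590; 2978 ± 1296 bp in 5 controls, 718 ± 942 bp in 3 cKO) and 1 near Polrmt, the mitochondrial RNA polymerase gene (chromosome 10, 79738518 to 79741245; 1772 ± 609 to 232 ± 402 bp). No promoter of 16872 passed with limma (1284 at an unadjusted p under 0.05), the smallest p being at Mab21l1 (-1.77 ± 0.35), Ier5l (-1.03 ± 0.20) and Bcap31 (-2.09 ± 0.43) on the shorter and at Zc3h11a (0 bp in every control, 679 ± 245 bp in cKO) on the longer side. The count of 8 regions rests on single libraries. It was 1 without control replicate 1, 0 without control 2, 3 without control 4, 2 without cKO replicate 1, and 0 without cKO 2 or cKO 3. Without control 3 it was 219, of which 140 were longer and 79 shorter, so the direction turned. Without control 5 it was 98, with 3 longer and 95 shorter. Numbers of H3K4me1 peaks were 132900 ± 41090 in controls and 139400 ± 9780 in cKO of the Kmt2a line (exact permutation p = 0.804). At a -log10 q of at least 10 the direction turned, with 28000 ± 9000 and 10000 ± 7883 peaks (exact permutation p = 0.0536) that covered 22.1 and 9.65 Mb (exact permutation p = 0.0357). They were 29280 ± 13940 and 23630 ± 20300 in the Kmt2b line (exact permutation p = 0.593).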

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

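The tests of sex labels, of promoter cover against cell types and peak numbers, and of the promoter difference between lines were chosen after the results were seen, and the comparison of single libraries with their group and the test of the line difference in expression were planned. In 10 of 152 groups of 4 to 10 libraries examined, 1 library lay far from the others; chance gives about 1 in 20. In CPM these were Sema3e in Kmt2a control 5 (92.64, others 116.5 to 125.2), Nts in Kmt2a cKO 4 (1.219, others 0 to 0.2868), Rxfp1 in Kmt2a cKO 4 (4.352, others 0.4006 to 1.263), Glra2 in Kmt2a control 5 (25.45, others 7.741 to 10.19), Pcdhb22 in Kmt2b control 7 (7.371, others 5.487 to 6.351) and Sord in Kmt2b control 5 (18.37, others 14.09 to 15.81). In bp of H3K4me3 cover they were Vmn1r129 in Kmt2b control 4 (753, others 0 to 136), Vmn1r100 in the same library (820, others 0 to 292) and Trim71 in Kmt2b cKO 2 (204, others 0), and in bp of H3K4me1 cover Fcgr3 in Kmt2b cKO 3 (637, others 0).

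Named genes whose cKO effect differed between the lines are given with the Kmt2a minus the Kmt2b log2 change. Genes that rose with loss of Kmt2a were Ntsr1 (1.24), Stra6 (1.13), Hes1 (1.53), Inpp4b (1.08), Nptxr (0.69), Cpne6 (0.64), Rtn4rl2 (0.76), C1qtnf12 (0.75) and Abca4 (1.74), and genes that fell with it were Sema3e (-1.02), March1 (-0.90), Robo1 (-0.61), Klhl13 (-0.69), Glra2 (-1.50), Scgn (-1.80), Kcnh7 (-0.99), Camk4 (-0.86), Serpina3n (-1.13) and Ugt8a (-0.90). Genes that fell with loss of Kmt2b were Ccdc91 (1.03), Hdx (1.25), Ano10 (0.65), Wdsub1 (1.01), Sord (1.21), Pole4 (0.74), Wdr17 (1.0), Eda (1.0), Hfm1 (1.83), Dazl (1.97), Slc9b2 (1.84), Igsf1 (2.77), Mapk3 (0.86), Irf1 (0.88) and Kl (1.23), and genes that rose with it were Dach2 (-3.71), Pramef8 (-0.73), Slc25a37 (-0.55), Clgn (-0.58), Atp2c2 (-1.69), Pcdhb20 (-0.52), Pcdhb17 (-0.59), Spink8 (-1.11) and Aqp4 (-0.79). Cdhr1 (2.67) changed in both, in opposite directions. Promoters shorter in the Kmt2b cKO differed by 3.21 (Col11a1), 2.57 (Eps15), 2.66 (Actrt3), 1.55 (Gjc1), 2.77 (Trim71) and 3.02 (Ang and Rnase4), on log2 lengths with 200 bp added, and Agbl2, at 0 bp in the Kmt2a cKO but not called there, by -1.43. In all, 790 genes and 589 promoters differed between the lines.

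No other grouping drawn gave as many genes as the real one in the Kmt2a line (136, highest of the other 99 groupings 58, so 1 of 100 reached it). The same held in the Kmt2b line (414, highest other 386, 1 of 100) and between the lines (790, highest other 3, 1 of 60). It also held for the Kmt2b H3K4me3 regions (2108, highest other 1210, 1 of 100) and promoters (2282, highest other 1042, 1 of 100). For the promoter difference between lines it held too (589, highest other 138, 1 of 100). Chance is thus unlikely for these counts, but a share under 1 of 100, or 1 of 60 between the lines in expression, could not be seen. The grouping with 386 genes kept 7 of the 11 cKO libraries together and was drawn without regard to the 2 alignment batches; a count that close to the real one points to a structure of the samples beside genotype. With the batch as a term 434 genes passed. The grouping with 1042 promoters set 5 of the 6 controls against the cKO libraries and 1 control, so it is close to the mirror of the real one. No gene passed for genotype by sex in expression of the Kmt2b line (edgeR 0, highest other 1, 60 of 60 groupings as large; 291 at an unadjusted p under 0.05, DESeq2 0). None passed for Kmt2a H3K4me3 regions (limma 0, highest other 86, 56 of 56; 2456 at an unadjusted p under 0.05), Kmt2a H3K4me3 promoters (limma 0, highest other 26, 56 of 56; 234) or Kmt2a H3K4me1 promoters (limma 0, highest other 0, 56 of 56; 1284). For the 8 Kmt2a H3K4me1 regions chance cannot be excluded: 12 of 56 groupings gave as many, and the highest, 4540, points to a structure of the samples other than genotype. For Kmt2b H3K4me1, 3 of 100 groupings gave as many regions as the real 1 (highest other 22) and 3 of 100 as many promoters as the real 1 (highest other 154); these pass the share set for chance, but the larger counts again point to a structure of the samples.

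The shorter H3K4me3 cover in the Kmt2b cKO was weighed against 3 technical explanations. Fewer tags or fewer peaks in total are excluded as the whole cause. With the same number of strongest peaks from every library 2281 promoters were shorter, and 2017 of all calls were shared with those of the full lists. With log2 tags as a covariate 2320 were shorter. The cKO lists held more peaks than the control lists, 56480 against 44080 on average, so equal numbers could hardly have removed the calls. Strong peaks, at a -log10 q of at least 10, were fewer in cKO, 13130 against 14680 (exact permutation p = 0.0823). Neither equal numbers nor the tag covariate tests that difference, so a part of it in the shorter cover stays open. Equal numbers do not match the width of peaks, which was not tested as a cause. Median width on autosomes was 392.7 bp in controls and 337.6 bp in cKO (exact permutation p = 0.0541). Among peaks with a -log10 q of at least 10 it was 1117 and 1116 bp (exact permutation p = 0.983). Fewer nuclei of other cells after the sort for neuronal nuclei may explain part of the pattern: promoters of non-neuronal marker lists were among the shorter, with a median log2 change of -0.886 for oligodendrocyte markers, the lowest of the 4 lists with a value among the 5 set for this test; microglia markers had too few tested promoters. Choroid plexus and ependymal markers, outside those 5, had -1.42. Lower cover was not limited to non-neuronal lists, with -0.706 for striatal and thalamic neuron markers and -0.95 for Hox and Meis genes. Markers of CA1, of CA2 and CA3, of dentate granule neurons and of interneurons had 0.0192, -0.17, -0.364 and -0.251. Fewer nuclei of other cells are excluded as the whole cause. Of the genes with a shorter promoter 161 were lower in unsorted tissue against 36.4 for independent sets, and none of the 5 lists passed as lower there in expression. The input of the cKO group is excluded as the whole cause by the expression of the same genes (camera p = 0.000499 with an estimated correlation), but at single promoters input and genotype cannot be told apart; a direct effect of losing Kmt2b stays a hypothesis.

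Sex-linked counts went against the labelled sex in 6 of 11 Kmt2a expression libraries (controls 4 and 5, cKO 2 to 5). An exchange of sex labels among libraries of the same genotype is a candidate explanation, as the numbers labelled female and the numbers with high Xist differed by 0 in each genotype. An exchange between genotypes is excluded by a score made without the library scored, which put all 11 on the side of their own label. Tissue of both sexes in 1 library is excluded, since Y-linked counts reached at most 0.18 CPM in libraries with high Xist. No biological explanation was tested, and the sex term in the Kmt2a expression comparison rests on these labels.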

How the results depend on the processing

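The replicate block, leave-one-out, normalization, filter, second tool, peak thresholds, equal peak numbers and pseudocount were chosen before the data were examined; the tests within sex, lane or batch, without the libraries with conflicting sex or with few peaks, and with tags as a covariate were chosen after. For the counts and tests that answer a comparison, 306 values under an alternative stayed on the same side or within 1.5 times of the main value, 76 moved, 1 became stronger and 1 reversed. For named genes and sites 1629 stayed the same, 324 passed no longer and 15 moved; in direction, none of the named genes and promoters reversed (190 of 683 values weaker in the Kmt2a line, 115 of 992 in the Kmt2b line, 17 of 234 for Kmt2b H3K4me3 promoters and 2 of 19 for Fcgr3). Where no cause is given, the cause was not tested.

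Genes passed in the Kmt2a line numbered 136 and under alternatives 909 with no filter, 499 with DESeq2, 545 in a fit of all 30 libraries, 2 in labelled females, 0 in labelled males (edgeR; 1143 at an unadjusted p under 0.05), 514 without the 6 libraries of conflicting sex, and 16 to 388 in leave-one-out. In the Kmt2b line the 414 became 181 in females, 11 in males, 0 in batch A (edgeR; 1262 at an unadjusted p under 0.05) and 161 in batch B, all with fewer libraries. The 790 genes that differed between lines became 455 with no filter, 1204 with DESeq2 and 350 to 1473 in leave-one-out. Gene lists past camera, 9 in the Kmt2a and 3 in the Kmt2b line, became 0 and 0 with an estimated correlation and 0 and 1 with fry. The 7 lists past camera on Kmt2b H3K4me3 promoters became 0 with an estimated correlation.

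With a block for the replicate number, which is not known to pair animals and was checked for pairing in the expression data alone, 61 genes passed in the Kmt2a and 196 in the Kmt2b line. Under the block H3K4me3 gave 4 regions and 1 promoter in the Kmt2a line and 2783 regions and 2440 promoters in the Kmt2b line. H3K4me1 under the block gave 1029 regions (394 longer and 635 shorter) and 0 promoters in the Kmt2a line. In the Kmt2b line it gave 0 regions and 1 promoter.

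H3K4me3 regions in leave-one-out numbered 0 to 6 in the Kmt2a line and 1329 to 2280 in the Kmt2b line. The 2108 Kmt2b regions became 1380 at a -log10 q of at least 10, 87 in females and 9224 in males (1558 shorter; 7666 longer, of which 3196 on autosomes, 465 on X and 4005 on Y), and the 2282 Kmt2b promoters 779 in females and 583 in males. The 8 Kmt2a H3K4me1 regions became 0 at a -log10 q of at least 10, 33 at a fold enrichment of at least 4, 67 with equal peak numbers, 3 with a peak required in at least 50% of the libraries of either group, 35 with a pseudocount of 50 bp, 0 with 1000 bp and 0 to 219 in leave-one-out; Kmt2a H3K4me1 promoters became 1 with equal peak numbers. The 1 Kmt2b H3K4me1 region became 2 at a -log10 q of at least 10, 2 at a fold enrichment of at least 4, 5 with equal peak numbers, 0 with a pseudocount of 1000 bp, 0 in females, 0 in males, 2606 without the 5 libraries under 20000 peaks and 0 to 5 in leave-one-out. The 1 Kmt2b H3K4me1 promoter became 2 with tags as a covariate, 0 in males, 0 without those 5 libraries and 1 to 11 in leave-one-out. The log2 ratio of the number of H3K4me1 peaks in the Kmt2a line went from 0.07 to -1.49 at a -log10 q of at least 10 (exact permutation p = 0.0536), past no threshold in either setting. That of the length covered by H3K4me1 in the Kmt2a line reversed from 0.18 to -1.20 at a -log10 q of at least 10 (exact permutation p = 0.0357, smallest possible 0.0179), and that of median width was 0.0763 to 0.245 in leave-one-out, with an exact permutation p of 0.0476 without cKO replicate 2. Of changes of 1.5 (log2) simulated at widely covered promoters, 6% were recovered for H3K4me1 in the Kmt2b line and 42% in the Kmt2a line. Lists of the Kmt2b line vary from 738 to 50932 peaks. Unique tags were more numerous in that line, 14.62 to 23.71 M against 4.61 to 12.81 M in the Kmt2a line. These values argue against fewer tags as the reason for the lower recovery in the Kmt2b line. Whether depth limits recovery within either line was not tested.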

Other observations

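The tests of gene lists on promoters, of the Oxr1 neighbourhood and batches, and of the Camk2a windows were chosen after the main results were seen. In the Kmt2b cKO, 7 gene lists passed camera for H3K4me3 promoter cover, and none of them passed with an estimated correlation (lowest adjusted p = 0.523), so the members called are given rather than the lists. Of 5 choroid plexus and ependymal markers with a tested promoter, Kl, Enpp2 and Prlr were shorter (camera adjusted p = 0.0158), and of 16 genes of interferon response and antigen presentation Ifit2, Irf1, H2-Q4 and H2-K1 were shorter (0.00287). Hoxd1, Hoxa9 and Pbx3 were shorter among 8 Hox and Meis genes (0.0308), and Itm2a and Kdr among 7 endothelial and mural markers (0.0438). Among 21 clustered protocadherin beta genes Pcdhb6 was longer (0.000229; median log2 change 0.282). In the Kmt2a cKO 0 of 15 of these promoters passed with limma for H3K4me3 (median 0.708, camera adjusted p = 0.000168, 0.997 with an estimated correlation) and 0 of 13 for H3K4me1 (median -0.723, camera adjusted p = 6.89e-05, 0.522 with an estimated correlation). That H3K4me1 comparison had other lists past camera with 0 members called by limma and an adjusted p of at least 0.522 with an estimated correlation, up for respiratory chain (median 0.71, 3.84e-06) and ribosomal protein genes (0.487, 0.000244) and down for activity-induced genes (-0.384, 0.000191), among others. For H3K4me3 in the Kmt2b cKO, ribosomal protein genes passed camera relative to other promoters (1 shorter of 57, median 0.009, camera adjusted p = 0.00721). So did nuclear genes of the respiratory chain (0 called of 40 by limma, median -0.00372, camera adjusted p = 0.0468), and both medians were near 0. In the same H3K4me3 comparison of the Kmt2b line 5 of 26 promoters of activity-induced genes were shorter, including those of Bdnf, Fosb, Jun and Dusp6 (camera adjusted p = 0.44). Of glutamate receptor genes 5 of 22 were shorter there, including Grin2c and Grin2d (camera adjusted p = 0.556).

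Peaks on the X chromosome made up 13.09 to 19.72% of H3K4me3 peaks in libraries labelled female and 3.16 to 6.16% in those labelled male. In H3K4me1 libraries the X share ran from 0.48 to 0.9% in females and from 0.42 to 2.13% in males of the Kmt2a line, so it does not tell the sexes apart there.

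For the lower Oxr1 expression in the cKO of both lines, the alignment batch of the Kmt2b libraries is excluded as the cause, with a log2 change of -1.07 within batch A. Of 7 other tested genes within 2 Mb, 0 passed the edgeR test in either line (lowest adjusted p = 0.288, Eif3e). A change of the whole neighbourhood as large as that of Oxr1 is thus unlikely. At a log2 change of 1 the test recovered 88 and 84% of simulated genes in the Kmt2a and Kmt2b lines. At 0.5 it recovered 40 and 68%, so a smaller change of the neighbourhood is not excluded. Traits that the cKO animals of both lines share apart from the deleted gene were not tested.

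A conditional knockout in CA neurons is often driven by a Camk2a promoter transgene, though the labels used here do not name the driver. Extra copies of that fragment would be in the cKO input as well, and cKO peaks were called over that input. It was therefore not known whether copies would add or remove peaks before the first base of Camk2a. In the 8 kb before it (chromosome 18, 60917307 to 60925306), H3K4me1 peaks covered 1281 ± 602 bp in 6 controls and 3966 ± 1708 bp in 5 cKO of the Kmt2b line (exact permutation p = 0.00649), while in the next 8 kb farther out they covered 291 and 80.4 bp (exact permutation p = 0.132). H3K4me3 cover of the same window was 329 bp in controls and 64.4 bp in cKO (exact permutation p = 0.0628). Because the direction that copies would give was not known, neither mark decides the question. Extra copies stay open as an explanation. In the Kmt2a line the window held 4465 ± 2053 and 4126 ± 3893 bp (exact permutation p = 0.875), and with 3 cKO libraries copies and none cannot be told apart. H3K4me3 cover of the window farther out was lower in the cKO of both lines, 523 against 169 bp in the Kmt2a line (exact permutation p = 0.0179, the smallest possible) and 504 against 40.8 bp in the Kmt2b line (exact permutation p = 0.00216, the smallest possible).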
